A study of Homo sapiens with 26 samples.

How the data were processed

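The series holds 26 libraries of total RNA from sorted human CD8, Tconv and Treg cells after transplant, with and without GVHD. Per the labels' protocols, RNA was extracted with Trizol and a micro column kit, and libraries were made with a strand-marking kit after ribosomal RNA was depleted. The authors deposited raw read counts per Ensembl gene, as whole numbers with no normalization. Per the submitters' processing notes, STAR 2.5.4a, featureCounts 1.5.1 and DESeq2 were used with the build GRCh38, with no role or order stated. The annotation release and the strand setting are not given in the sources used here, so overlapping and antisense genes are uncertain.

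The table held 60623 gene IDs and 27 columns of counts. The 1 column that matched no sample label was not used. Groups came from the sorted cell type and disease state in the labels. The labels do not say whether a patient gave more than 1 subset, so p-values treat libraries as independent, and no pairing was used. Genes of the Y chromosome, XIST and TSIX were removed, 512 IDs in all, which left 60111. Coordinates, biotypes and GC content came from GENCODE v29 on GRCh38, which covered 58005 of the IDs kept. The 45 pairs of libraries within groups correlated between 0.917 and 0.987 and all differed by more than sampling noise, the lowest chi-square per gene being 30.7.

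Genes were filtered with filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested with edgeR 4.0.16's quasi-likelihood test in R 4.3.3, within each subset and, for differences between subsets, in 1 fit of all 26 libraries with 6 group means. Adjusted p is Benjamini-Hochberg with a threshold of 0.05. The SE of a log2 fold change was taken from the test's F statistic. Group means of named genes are TMM-scaled CPM. The CPM of CD8A, CD4 and FOXP3 in whole subsets and of MALAT1, RN7SL1, ACTB and HBB use the total count. Depth is the total count per library, from 23679634 to 46489436, so that 1 CPM stands for 23.7 to 46.5 counts.

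Gene lists, 43 in number, were written before the data were examined, and those with at least 5 measured members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. Counts of members adjusted over a list alone make no allowance for the number of lists, nor for a list picked because it led its comparison. Camera's preset correlation treats genes of a list as nearly independent, and splits of the libraries that ignore GVHD call about as many lists.

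Named genes followed a rule set before the data were examined. For each GVHD comparison the protein-coding genes with mean log2 CPM above 0 that passed were named, up to 10 each way, and where fewer than 20 passed also the 10 of smallest p among the rest. Up to 4 members of smallest p were named for each list called or holding a called gene, with FOXP3, IL2RA, CTLA4, IKZF2, CD4, CD8A and CD8B as sort checks. Antigen receptor segments and genes with common deletions or copy variants were left out of the first part of the rule. Not every gene that the rule gives is printed, and those printed were picked from it after their values were seen, not by order of p. For subset comparisons the sort genes and the 5 highest and 5 lowest folds were taken.

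The alternatives were DESeq2's size factors, the DESeq2 1.42.0 Wald test, limma voom with sample weights, no filter on low counts, a filter of 1 CPM in a fixed share of libraries, a robust fit, a joint fit and leaving out each library. After the data were seen, the MALAT1 class as a term, fits within a class and exact permutation of list means were added. The edgeR and camera steps were tested on simulated counts with 200 changed genes and known folds. At 2-fold, 15.5% of changed genes were recovered for CD8 (17686 genes), 16.3% for Tconv (17350 genes) and 40% for Treg (18736 genes). At 4-fold, 67%, 70.8% and 77.1% were recovered, with 6, 4 and 7 unchanged genes called. Simulated genes were drawn independently, so the correlation between genes of a list was not tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.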

Results

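Gene expression was measured by RNA sequencing in T cell subsets sorted from people after a transplant that used post-transplant cyclophosphamide, a drug given to limit graft-versus-host disease (GVHD), in which donor T cells attack the recipient's tissues. The 26 libraries fell into 6 groups. CD8 T cells, the cytotoxic subset, gave 5 libraries with GVHD and 4 without. Conventional CD4 T cells (Tconv), the helper subset, gave 5 with GVHD and 5 without. Regulatory T cells (Treg), the suppressive CD4 subset that depends on FOXP3, gave 3 with GVHD and 4 without. The total count per library ran from 23679634 to 46489436. The comparisons asked which genes differed with GVHD within each subset, and whether that difference varied between subsets.

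The sorted subsets carried the genes that define them. CD8A averaged 1695 ± 445 CPM (SD, n = 9) in CD8 cells, against 1.49 ± 2.01 (SD, n = 10) in Tconv and 1.02 ± 0.701 (SD, n = 7) in Treg. CD4 averaged 591 ± 205 CPM (SD, n = 10) in Tconv and 0.878 ± 0.569 (SD, n = 9) in CD8 cells. FOXP3, the transcription factor that specifies regulatory T cells, averaged 380 ± 98.3 CPM (SD, n = 7) in Treg and 3.52 ± 2.16 (SD, n = 10) in Tconv. In Treg against Tconv, FOXP3 was higher by 6.65 ± 0.42 on the log2 scale (SE; adjusted p = 1.56e-10, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). IL2RA, the high-affinity chain of the interleukin-2 receptor, was higher by 4.07 ± 0.40, and the inhibitory receptor gene CTLA4 by 2.84 ± 0.41. CD40LG, the helper cell ligand of CD40, was lower in Treg, at 7.05 ± 2.01 CPM (SD, n = 7) against 85.3 ± 22.8 (SD, n = 10) in Tconv. Across 21970 genes tested by edgeR, 4889 differed between Treg and Tconv, of which 2118 were higher in Treg. With the library classes described below as a term, the count was 3058.

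In CD8 cells against Tconv, CD8A was higher by 10.37 ± 0.66 on the log2 scale and CD8B by 9.23 ± 0.61. KLRK1, which encodes the activating receptor NKG2D, was higher by 8.94 ± 0.62, and its reads can be shared with the readthrough gene KLRC4-KLRK1. CD4 was lower, with a log2 fold change of -9.31 ± 0.42, and CD40LG with -6.09 ± 0.30. In this contrast 3633 of 21970 genes differed by edgeR's quasi-likelihood test, and 1827 of them were higher in CD8 cells.

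The libraries also separated by MALAT1, a nuclear long noncoding RNA. It was between 5134 and 12035 CPM in one class of libraries and between 21388 and 39623 CPM in the other. All 7 Treg libraries were in the high class. Among Tconv, 3 of the 5 libraries with GVHD and 1 of the 5 without were high, and among CD8 cells 1 of 5 and 1 of 4. RN7SL1, the RNA of the signal recognition particle, averaged 14220 ± 4282 CPM (SD, n = 7) in Treg and 28670 ± 13730 (SD, n = 9) in CD8 cells. ACTB, the gene of beta-actin, stood at 1372 CPM in Tconv GVHD replicate 5 and 1985 CPM in CD8 GVHD replicate 5, the lowest value of each subset. HBB, a globin gene of red blood cells, was between 8.17 and 29.2 CPM in CD8 GVHD replicates 2 to 5, while the highest value in any other library was 1.28 CPM.

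**Figure D1:**
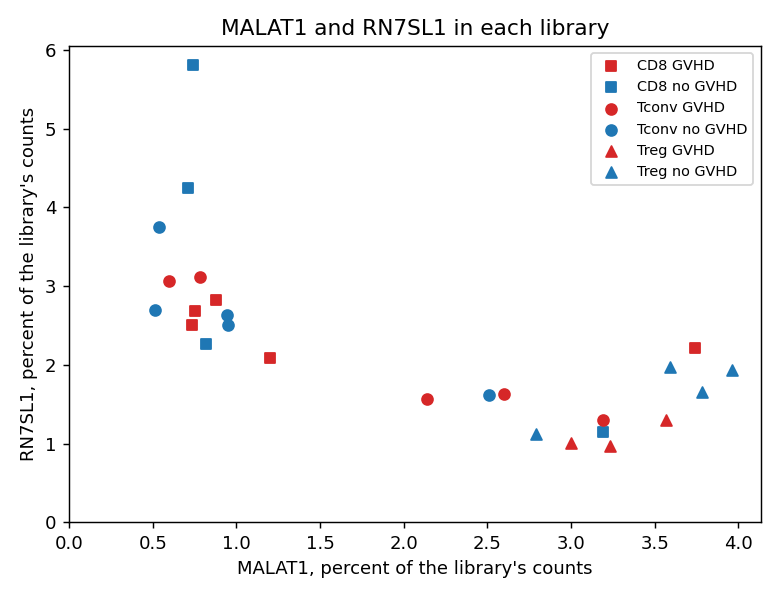
MALAT1 (horizontal axis) and RN7SL1 (vertical axis) as percent of each library's counts. Each point is 1 library, with the subset given by its shape and GVHD status by its color. MALAT1 runs from 0.513 to 1.2 percent in the low class and from 2.14 to 3.96 percent in the high class.

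In Tconv, 17 of 17824 genes passed edgeR's quasi-likelihood test, 12 lower and 5 higher with GVHD. LRRN3, a leucine-rich repeat gene on the fixed list of naive and central memory genes, fell from 51.8 ± 17.7 to 8.82 ± 3.03 CPM (SD, n = 5 in each group), a log2 fold change of -2.55 ± 0.30 (SE; adjusted p = 0.0285, edgeR). IKZF2, which encodes the Ikaros family factor Helios, fell from 38.7 ± 16.7 to 6.49 ± 2.28 CPM (adjusted p = 0.0376, edgeR). TMIGD2, a costimulatory receptor gene, fell from 30.4 ± 12.7 to 5.80 ± 1.90 CPM (adjusted p = 0.035, edgeR). AFDN, which encodes the junction protein afadin, rose from 18.2 ± 3.73 to 56.3 ± 16.1 CPM, and the cyclic AMP phosphodiesterase gene PDE4A from 6.07 ± 1.86 to 19.9 ± 5.71 CPM.

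LRRN3 lies on chromosome 7 at 111091006 to 111125454, IKZF2 on chromosome 2 at 212999691 to 213152427, and AFDN on chromosome 6 at 167826922 to 167972023, on GRCh38. The other protein-coding genes named by the rule that fell were PDE9A (-3.11 ± 0.42), AIF1 (-3.04 ± 0.44), ARHGAP32 (-3.82 ± 0.60), CD248 (-4.26 ± 0.59), SDK1 (-4.63 ± 0.75), CACHD1 (-5.49 ± 0.85) and DACH1 (-6.09 ± 0.92). In the libraries with GVHD, CD248, SDK1, CACHD1 and DACH1 averaged under 1 CPM, so the size of their fold depended on few counts. GDPD5 (1.46 ± 0.22) and RRBP1 (1.03 ± 0.16) rose. The 3 called genes outside the rule, named after their values were seen, were ANKRD50, LINC00299 and LEF1-AS1. LEF1-AS1 overlaps an end of LEF1 on the other strand, and whether strand was used in counting is not given in the sources used here. Of the genes under the rule that did not pass, the smallest p belonged to SSTR3 (-2.66 ± 0.46, adjusted p = 0.0719, edgeR), CR2 (-3.46 ± 0.60, adjusted p = 0.0751) and AEBP1 (-2.52 ± 0.44, adjusted p = 0.0762).

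Of the libraries with GVHD, 3 of 5 were high in MALAT1, against 1 of 5 without, and leaving out single libraries changed the call. No gene passed without Tconv GVHD replicate 2, 4 or 5 or without Tconv no-GVHD replicate 1 or 4, 1 gene passed without GVHD replicate 1 or 3 or no-GVHD replicate 2, and 53 passed without no-GVHD replicate 5. Without no-GVHD replicate 3, 17 passed, of which 9 were among the original 17. No gene passed edgeR's test with the MALAT1 class as a term (1063 at an unadjusted p under 0.05) or within the low class, 2 libraries against 4 (1160), whereas without the class the DESeq2 Wald test called 220 genes and voom with sample weights 151.

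Some called genes belong to other fixed lists. IKZF2 is on the lists of Treg core, Treg sort and coinhibitory genes, where it was the 1 member called over all genes. Its fellow Treg sort genes RTKN2 (-1.08 ± 0.35), FOXP3 (-0.14 ± 0.52), IL2RA (0.04 ± 0.50) and CTLA4 (0.52 ± 0.53) did not pass. The Treg sort list had a median of -0.24 over 5 members and was not called (camera adjusted p = 0.11). AIF1 is on the list of monocyte and dendritic cell markers, whose median was 0.05 over 20 members, with 1 lower when adjusted over the list alone.

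**Figure D2:**
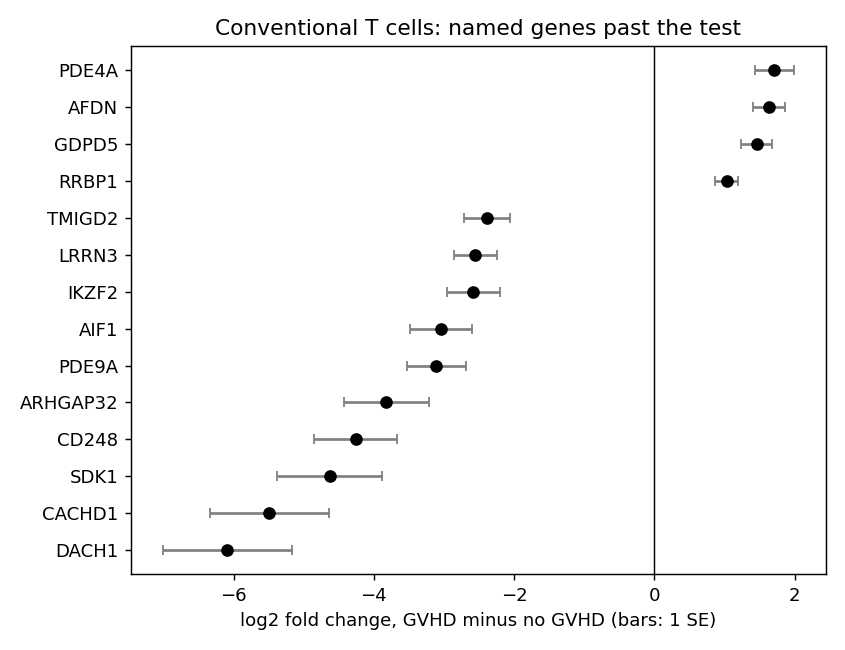
Log2 fold change (horizontal axis, GVHD minus no GVHD, 5 libraries in each group) of the 14 named protein-coding genes past the test in Tconv, with bars of 1 SE. Folds run from -6.09 for DACH1 to 1.71 for PDE4A.

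Of the 22 measured naive and central memory genes in Tconv, 21 had a fold below 0 and the median was -0.82. LRRN3 was the 1 member called over all genes. When adjusted over the list alone, without allowance for the number of lists, 9 members were lower. ACTN1 (-2.81 ± 0.52), PECAM1 (-2.66 ± 0.53) and LEF1 (-1.03 ± 0.29), a transcription factor gene of naive T cells, did not pass over all genes. Of the Tconv libraries, 3 of 5 with GVHD and 1 of 5 without were high in MALAT1, and with that class as a term the median was -0.53 (-0.76 to -0.29 without single libraries). With that term camera still called the list at the preset correlation (adjusted p = 1.3e-06). Without the term the list was called by camera (adjusted p = 1.5e-09) and not with an estimated correlation (adjusted p = 0.71). Type I interferon genes had a median of -0.68 over 33 members, with camera adjusted p = 0.0049 and adjusted p = 0.85 with an estimated correlation. IFI44L ranged from 15.6 to 1369 CPM among the libraries without GVHD. Cytotoxic effector genes had a median of 0.85 over 26 members (camera adjusted p = 0.013, and 0.85 with an estimated correlation). KLRD1, an NK receptor gene, ranged from 0.751 to 373 CPM among the libraries with GVHD. NK cell markers, a list that shares KLRD1, had a median of 0.71 over 12 members, 7 with a fold above 0, and were not called (camera adjusted p = 0.095). Within the low-MALAT1 libraries, 2 against 4, the cytotoxic median was -0.63. With the MALAT1 class as a term it was 0.76 (camera adjusted p = 0.033). The type I interferon median was then -0.92 (camera adjusted p = 5.6e-08) and the Th1 median 0.62 (camera adjusted p = 0.0081), all with the preset correlation. Th1 genes (median 0.76), cell cycle genes (0.59), ribosomal protein genes (-0.37, a list fixed as a check of RNA quality) and B cell markers (-0.77) were the other lists called. With an estimated correlation the adjusted p was 0.85 for the first 3 and 0.73 for B cell markers. With the MALAT1 class as a term the call was lost for ribosomal proteins (median 0, camera adjusted p = 0.95), cell cycle genes (0.22, adjusted p = 0.091) and B cell markers (-0.71, adjusted p = 0.074).

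The ribosomal protein list, fixed as a check of RNA quality, was called by camera in each subset. All 43 members had a fold below 0 in CD8 cells and Tconv and above 0 in Treg, so a difference in RNA quality was not excluded. In all, camera called 7 of the lists in Tconv, 7 in CD8 cells and 11 in Treg. Groupings of the same libraries that ignored GVHD gave about as many, with a median over the other splits of 9 lists in Tconv, 7 in CD8 cells and 10 in Treg. With an estimated correlation, and in exact permutation tests of each list's mean per library, 0 lists were called in any subset after adjustment. The few relabelings left the permutation little room for a call. Its smallest p was 0.0079 in CD8 cells (B cell markers) and in Tconv (Notch genes), and 0.029 in Treg (NK cell genes). After adjustment these were 0.32, 0.31 and 0.56, so its 0 calls do not decide against a list.

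In CD8 cells, no gene among 18198 passed edgeR's quasi-likelihood test, with 584 at an unadjusted p under 0.05. The DESeq2 Wald test called 32 genes and voom with sample weights 2. Among the protein-coding genes with mean log2 CPM above 0, to which the naming rule applies, the smallest p belonged to CD79A, a B cell receptor component, at 1.41 ± 0.771 CPM (SD, n = 5) with GVHD and 6.93 ± 1.58 (SD, n = 4) without (adjusted p = 0.734, edgeR). The complement receptor genes CR1 (-2.78 ± 0.53) and CR2 (-4.51 ± 1.0), and FHIT (-1.44 ± 0.30), were among the 10 of smallest p under the same rule and did not pass. CD79A and CR2 are both on the fixed list of B cell markers. B cell markers had a median of -1.13 over 11 members, of which 0 were called over all genes and 4 were lower when adjusted over the list alone (camera adjusted p = 3.2e-08; adjusted p = 0.11 with an estimated correlation). MS4A1, which encodes CD20, was at 0.747 CPM with GVHD and 5.04 CPM without, and reached 16.4 CPM in the highest library.

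Naive and central memory genes in CD8 cells had a median of -0.41 over 22 members, with 0 called over all genes and 2 lower when adjusted over the list alone (camera adjusted p = 1.8e-06; adjusted p = 0.63 with an estimated correlation). ACTN1 had a fold of -2.75 ± 0.64 and LRRN3 of -3.56 ± 0.96. Immediate early and AP-1 genes had a median of -0.41 over 29 members (camera adjusted p = 1e-04; adjusted p = 0.95 with an estimated correlation). Interferon gamma genes had a median of 0.34 over 24 members (camera adjusted p = 0.0011; adjusted p = 0.88 with an estimated correlation), and CIITA, the regulator of class II genes, had a fold of 0.68 ± 0.26. The remaining called lists were Treg core genes (median -0.50), Treg sort genes (-1.06) and ribosomal proteins (-0.24), with adjusted p = 0.23, 0.23 and 0.97 with an estimated correlation. The Treg sort list had 5 members, all also on the Treg core list. FOXP3 averaged 0.777 CPM with GVHD and 1.015 without, and IL2RA 0.898 and 1.536. CTLA4 had a fold of 0.03 ± 0.55, RTKN2 of -2.03 ± 0.49 and IKZF2 of -2.57 ± 0.77. IKZF2 ranged from 20.9 to 425.6 CPM among the CD8 libraries without GVHD. With the MALAT1 class as a term the call of the Treg core list was lost (median -0.55, camera adjusted p = 0.064). Without CD8 no-GVHD replicate 3 the ribosomal protein median was -0.01 and camera's direction turned.

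In Treg, no gene among 19379 passed edgeR's quasi-likelihood test, with 1523 at an unadjusted p under 0.05. The DESeq2 Wald test called 117 genes and voom with sample weights 0. PLAC8 was at 58.1 CPM without GVHD, with a fold of -2.05 ± 0.22 (adjusted p = 0.0688, edgeR). ZBTB10 had a fold of -2.39 ± 0.28. BACH2, a transcriptional repressor that restrains effector differentiation, was at 22.1 CPM with GVHD and 69.0 without (-1.64 ± 0.24, adjusted p = 0.137, edgeR). FOXP3 (0.11 ± 0.25), IL2RA (-0.04 ± 0.34) and CTLA4 (-0.26 ± 0.20) had folds within 2 SE of 0.

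Of 29 immediate early and AP-1 genes in Treg, 27 had a fold below 0, with a median of -0.69. None was called over all genes. When adjusted over the list alone, without allowance for the number of lists, 16 were lower. The AP-1 subunit gene JUN was at 81.5 CPM with GVHD and 259 without (-1.67 ± 0.22, adjusted p = 0.107, edgeR), FOSB had a fold of -1.17 ± 0.16 and FOS of -1.79 ± 0.34. The list was called by camera (adjusted p = 4e-13) and not with an estimated correlation (adjusted p = 0.41). Naive and central memory genes had a median of -0.26 over 22 members, with 0 called over all genes and 6 lower when adjusted over the list alone (camera adjusted p = 0.00044; adjusted p = 0.41 with an estimated correlation). CCR7, the lymph node homing receptor gene, had a fold of -1.31 ± 0.32, and TCF7 of -1.08 ± 0.27. Cytotoxic effector genes had a median of 0.78 over 26 members (camera adjusted p = 0.00016; adjusted p = 0.83 with an estimated correlation), with EOMES at 2.72 CPM with GVHD and 0.197 without. NF-kB genes (-0.20) and Notch genes (-0.16) were the other lists called as lower. Ribosomal proteins (0.29, the RNA quality list), oxidative phosphorylation (0.20), interferon gamma (0.29), NK cell (0.58), cell cycle (0.34) and glycolysis genes (0.16) were called as higher. Their adjusted p with an estimated correlation ran from 0.41 to 0.96. The cell cycle median was -0.09 without Treg GVHD replicate 1.

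**Figure D3:**
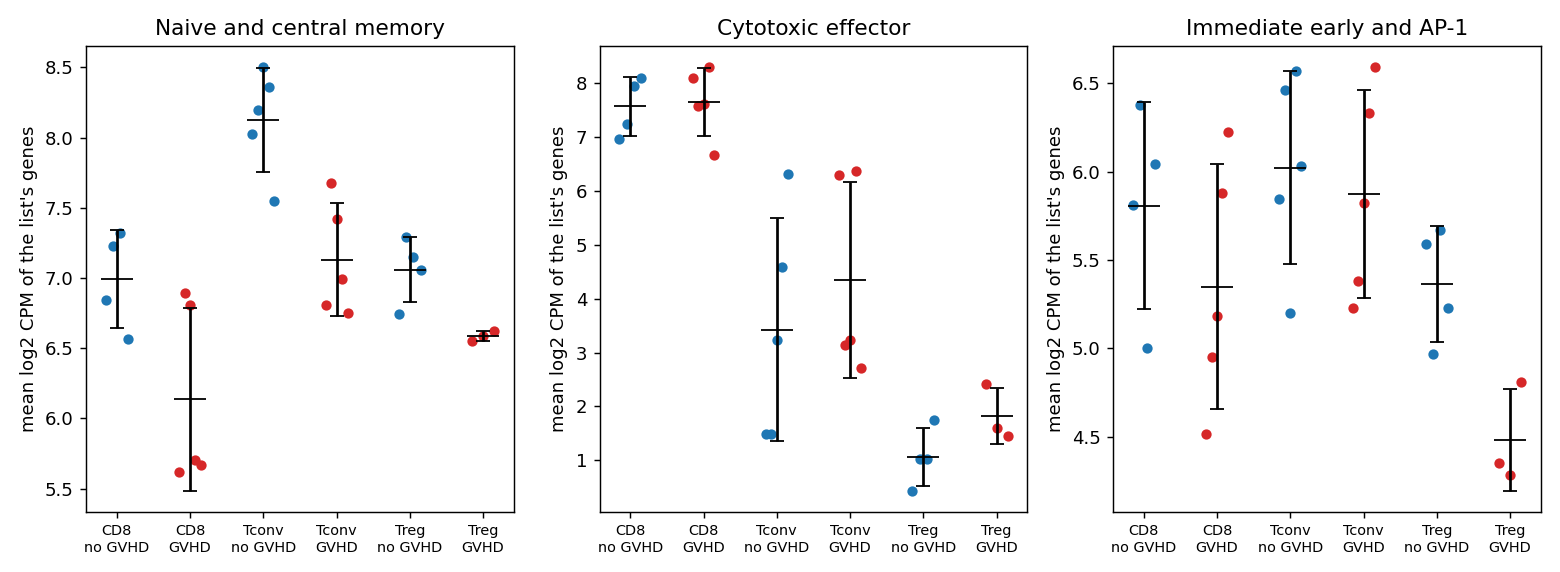
Mean log2 CPM of the genes of 3 lists (vertical axes) in each library, by subset and GVHD status on the horizontal axes. Points are libraries, and bars give the group mean and 1 SD. In Treg the immediate early and AP-1 mean lies between 4.28 and 4.81 in the 3 libraries with GVHD and between 4.97 and 5.67 in the 4 without.

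No gene passed edgeR's test of a GVHD change that differed between subsets, over 21970 genes in a fit that treated all libraries as independent. At an unadjusted p under 0.05 there were 490 genes for CD8 cells against Tconv, 634 for Treg against Tconv and 506 for CD8 cells against Treg. The DESeq2 Wald test called 4, 4 and 3 genes. The labels name no patient, so any sharing of patients between subsets was left out of this fit, and its lack of calls does not show that the changes were alike. For a gene called in Tconv and in no other subset, such as LRRN3, whether the change differs between subsets stays open.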

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

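The tests of GVHD status and depth for the MALAT1 classes, of the MALAT1 class for the naive genes, of glucocorticoid exposure, of list differences between subsets and of permuted list means were chosen after the results were seen, and the bounds for leaving out a library were set after the medians were seen.

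In 103 tests of a measure within a group of 4 or 5 libraries, over 48 measures, 11 found a library far from the others. Chance gives about 1 in 20 for a single test. The tests share libraries and include genes and lists called on them, so whether 11 is an excess was not tested. Tconv no-GVHD replicate 5 had 36700 genes with a count against 23270 to 25290 in its group, a log2 CPM of 0.69 for ARHGAP32 against 3.90 to 4.97, and of 1.55 for LEF1-AS1 against 3.78 to 4.14. CD8 no-GVHD replicate 1 had a MALAT1 log2 CPM of 14.96 against 12.8 to 13, and 0.77 percent mitochondrial mRNA against 0.65 to 0.67. ACTB was low in Tconv GVHD replicate 5 (log2 CPM 10.42) and CD8 GVHD replicate 5 (10.96). The other values were the mean of the Treg core list in CD8 no-GVHD replicate 4 (3.07), that of ribosomal proteins in CD8 GVHD replicate 1 (9.25), CD248 in Tconv GVHD replicate 1 (-4.06) and LEF1-AS1 in Tconv GVHD replicate 3 (-0.40).

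Camera called 25 of 123 list differences between subsets, and 1 held with an estimated correlation. It was B cell markers, whose GVHD change in CD8 cells lay -1.87 from that in Treg (adjusted p = 0.013 with an estimated correlation). Some of these markers had few counts in CD8 cells, with FCRL1 at 0.086 CPM with GVHD and 0.936 without. MS4A1 ran from 0.521 to 16.4 CPM among the CD8 libraries without GVHD. In Tconv without GVHD, CR2 averaged 15.2 CPM and MS4A1 1.14, so the list may not stand for B cells alone. For CD8 less Tconv the median differences were -0.75 for cytotoxic genes, -0.29 for activation markers, -0.37 for cell cycle, -0.28 for Treg core, -0.52 for Th1, -0.63 for Th17, -0.25 for AP-1, 0.25 for Notch, -0.99 for NK cell, 1.07 for erythroid and -1.10 for neutrophil and progenitor genes. For Treg less Tconv they were -0.81 for Th1, -0.64 for Tfh, -0.60 for AP-1, 0.33 for oxidative phosphorylation, 1.64 for B cell and 0.68 for ribosomal protein genes. For CD8 less Treg they were -0.38 for Treg core, 0.35 for AP-1, -0.31 for oxidative phosphorylation, -0.44 for monocyte, -1.11 for NK cell, -1.14 for Treg sort and -0.51 for ribosomal protein genes.

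The split of the libraries by MALAT1 did not fully match GVHD status in the CD8 and Tconv sorts, since 8 of the 19 libraries broke the closer rule. That rule can exclude only a full match. A partial link was not tested, and in Tconv 3 of 5 libraries with GVHD and 1 of 5 without were high. The exact permutation p of the difference in depth between the classes was 0.59 over 7560 relabelings, two-sided, and as the high class did not span the low class depth stays open. Across genes, the class fold correlated with transcript GC content with Spearman rho = -0.29, between the bounds set beforehand, so GC content may be part of the split. All 7 Treg libraries were in the high class, so in that sort class and cell type cannot be told apart. No batch is named in the labels.

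The lower naive and central memory genes in Tconv with GVHD kept a median of at most -0.70 without any 1 library, and of -0.76 less the trend on GC content (jackknife SE 0.30), which argues against a single library and against that trend as the whole cause. With the MALAT1 class as a term the median was -0.53 (jackknife SE 0.36) and ran from -0.76 to -0.29 as single libraries were left out, so the class stays open as part of it. The exact permutation p of the list mean was 0.016 over 252 relabelings, two-sided, and 0.31 after adjustment over the lists. The smallest permutation p of any list in Tconv, 0.0079 for Notch genes, was also 0.31 after adjustment, so the adjusted value cannot decide. As the list was picked because it led this comparison, chance stays open, as does GVHD itself.

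The lower immediate early and AP-1 genes in Treg kept a median of at most -0.51 without any 1 library. The exact permutation p was 0.057 over 35 relabelings, two-sided, where the smallest possible is 0.029, so a grouping of the 3 and 4 libraries by chance was not excluded. The glucocorticoid list had a median of 0.03 (jackknife SE 0.31), and 2 of 5 marker genes had a fold above 0, which leaves glucocorticoid exposure open. Handling of cells can also induce these genes and was not tested, and GVHD itself stays open.

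Other splits of the libraries bore on each count. For Tconv, 2 of 100 splits called at least the real 17 genes, and the highest of the others called 73. That split kept 4 of the 5 GVHD libraries in 1 arm and had 2 high-MALAT1 libraries in each. As it called several times the real count it points to a structure of the samples. The 2 of 100 met the bound set beforehand against chance. The count still ran from 0 to 53 as single libraries were left out, which does not measure chance but shows how much the count rested on single libraries. For that reason chance was not taken as excluded for the count of 17. Any split reaches a count of 0, so the splits say nothing about chance for the 0 genes of CD8 (100 of 100 splits, highest other 1) or of Treg (35 of 35, highest other 2). For lists, 70 of 100 splits reached the 7 of CD8 (highest other 14), 65 of 100 the 7 of Tconv (highest other 17) and 15 of 35 the 11 of Treg (highest other 23), so chance was not excluded for any. The same holds for the interaction counts of 0 (90 of 90 relabelings each), where the highest other was 1910 for CD8 against Tconv, which points to a structure of the samples, and 1 for each of the others. Between subsets, 1 of 90 relabelings reached 4889 genes for Treg against Tconv (highest other 41) and 1 of 90 reached 3633 for CD8 against Tconv (highest other 1943), which excludes chance.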

How the results depend on the processing

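The alternatives with the MALAT1 class as a term, within a class and by exact permutation of list means were chosen after the results were seen. No paired analysis was run, since the labels tie no library to a patient and the replicate numbers were given in the order of deposit. Within each subset that is also the order of the title numbers, with GVHD before no GVHD, and no title names a patient. Some values, picked by eye and not tested, ran in parallel between CD8 and Tconv libraries of the same number, which is a hint and not a stated pairing. With GVHD, the immediate early and AP-1 mean rose with the number in both, from 4.51 to 6.22 in CD8 and from 5.23 to 6.59 in Tconv, and the cytotoxic means ranked the numbers alike. ACTB was low in GVHD replicate 5 of both (1985 and 1372 CPM) and MALAT1 high in no-GVHD replicate 1 of both (31900 and 25076 CPM). Independence between subsets is therefore not assured, and the lack of interaction calls is left open. If libraries of different subsets come from the same patients, the tests between subsets have the wrong spread. Of 245 counts of calls under alternatives, 202 stayed within 1.5 times the reported value, 23 were lower and 20 higher. Counts of 0 that stayed 0, as for the interactions, are among the 202. That total therefore says little of the 17 Tconv genes, whose count ran from 0 to 53 without single libraries. Of 2728 folds of named genes, 2382 kept direction and side of the threshold and 61 changed sign, and of 320 values of called lists 217 and 5 did. The 17 Tconv genes kept their direction without each single library, with the class term and within the low class, but they were chosen as called on these same libraries. The fit within the high class sets 3 GVHD libraries against 1 without, which is assumed to vary like the others, so its values are differences from that 1 library and say nothing of stability. The CPM filter tested 14 of the 17 and called all 14. The cause of each change given here was not tested, except that fits within a class, or without a library, have fewer libraries. The depth behind 1 CPM limits genes under 1 CPM to few counts.

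With the DESeq2 Wald test, 32 genes were called in CD8, 220 in Tconv and 117 in Treg, and 4, 4 and 3 in the interactions of CD8 with Tconv, Treg with Tconv and CD8 with Treg. With voom and sample weights there were 2 in CD8 and 151 in Tconv. With no filter on low counts there were 17 in CD8, 199 in Tconv, 199 in Treg and 1 in the interaction of CD8 with Tconv. The robust fit called 2 in Treg and the joint fit 58 in Tconv, of which 11 were among the 17. With the MALAT1 class as a term the count was 0 in Tconv and 3058 between Treg and Tconv, and it was 0 in Tconv within the low class (2 libraries against 4) and 0 within the high class (3 against 1). With an estimated correlation, 0 lists were called in CD8, 0 in Tconv and 0 in Treg. With fry there were 0, 1 and 0, and with exact permutation 0, 0 and 0, where the few relabelings left little room for a call. The 1 list of fry was Notch genes (fry adjusted p = 0.044, median -0.22), which camera did not call in Tconv (adjusted p = 0.11). With the class as a term the Notch median was -0.03.

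Without single libraries, called genes ran from 0 to 0 in CD8, from 0 to 53 in Tconv and from 0 to 1 in Treg, where the 1 came without no-GVHD replicate 1. The Tconv count was 0 without GVHD replicates 2, 4 or 5 or no-GVHD replicates 1 or 4, 1 without GVHD replicates 1 or 3 or no-GVHD replicate 2, and 53 without no-GVHD replicate 5. The counts ran from 2901 to 3962 for CD8 against Tconv and from 3486 to 5545 for Treg against Tconv, and each interaction stayed at 0. Called lists ran from 4 (without GVHD replicate 1) to 13 (without no-GVHD replicate 1) in CD8 and from 9 to 12 in Treg. In Tconv they ran from 4 (without no-GVHD replicate 1) to 12 (without no-GVHD replicate 5), with 11 without GVHD replicate 5.

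Signs changed mostly for genes whose fold lay near 0. Among those further from 0 in the main fit were GZMB (2.53 ± 1.19), IL18RAP (2.35 ± 0.99) and CCL4 (1.85 ± 1.35) in Tconv. Their signs turned with the MALAT1 class as a term and within the low class. With voom the fold in CD8 was -0.54 for CTLA4, 0.38 for CD4, 0 for CD8A and 0.11 for CD8B. In Tconv it was -0.27 for CTLA4, 0.25 for FOXP3, 0.32 for CD4 and -0.28 for CD8A, and in Treg 0.01 for IL2RA and -0.32 for CD8A. CD4 in Treg was at 0 with DESeq2's size factors, 0 with the DESeq2 Wald test and -0.01 with the CPM filter. With the MALAT1 class as a term, folds in Tconv were -0.88 for GZMB, -0.96 for CCL4, -0.16 for IL18RAP, -0.48 for CTLA4, 0.24 for CD4 and -0.57 for CD8A, and the ribosomal protein list was at 0. Within the low class they were -2.33 for GZMB, -2.41 for CCL4, -1.47 for IL18RAP, -1.17 for CTLA4, 0.10 for FOXP3, 0.25 for CD4 and -1.93 for CD8A, with -0.63 for the cytotoxic list. Within the high class, against 1 library, they were 0.43 for GZMM, 0.08 for RPL23, 0.03 for RPL32, 0.17 for RPS23, -1.61 for IL2RA and 0.23 for CD4, with 0.24 for the ribosomal protein list.

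Where leaving out 1 library changed a sign, the folds over all single libraries left out ran, for the CD8 cells, from -0.43 to 0.46 for CTLA4, from -0.24 to 0.22 for CD8B, from -0.05 to 0.35 for CD8A and from -0.79 to 0.23 for CD4 in CD8. In Tconv they ran from -0.31 to 0.27 for IL2RA, from -0.32 to 0.07 for CD4, from -0.38 to 0.40 for FOXP3, from -0.05 to 0.84 for CTLA4 and from -0.30 to 1.71 for CD8A. In Treg they ran from -0.04 to 0.07 for CD4, from -0.21 to 0.45 for IL2RA, from -0.73 to 0.70 for CD8A and from -0.04 to 0.39 for FOXP3. The median of ribosomal proteins in CD8 ran from -0.62 to -0.01, and camera's direction for it turned without no-GVHD replicate 3 (-0.01). The median of cell cycle genes in Treg ran from -0.09 (without GVHD replicate 1) to 0.62.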

Other observations

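None of the tests in this part was chosen after its result was seen. In Tconv, genes of the coinhibitory and Treg core lists had folds of both signs with GVHD, and camera called neither list. IKZF2, which was lower, was the 1 member of each called over all genes. PRDM1, which encodes the repressor Blimp-1, was at 326 ± 206 CPM with GVHD and 122 ± 63.7 without (SD, n = 5 in each group), a log2 fold change of 1.42 ± 0.44 that did not pass (adjusted p = 0.419, edgeR). TNFRSF18, which encodes the receptor GITR, had a fold of 1.76 ± 0.39 and BTLA, an inhibitory receptor gene, of 0.60 ± 0.20, and neither passed. The coinhibitory list had a median of -0.03 over 19 members and camera adjusted p = 0.73, with adjusted p = 0.91 with an estimated correlation. Over the list alone 3 members were higher and 1 lower. The Treg core list had a median of 0.07 over 24 members (camera adjusted p = 0.57), with 1 higher and 1 lower over that list alone.

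Among the largest differences between sorted subsets, FANK1 was higher in Treg than in Tconv by 7.43 ± 0.55 on the log2 scale and WSCD2 by 6.87 ± 0.77. PDZD4 was lower, at 0.901 ± 0.669 CPM (SD, n = 7) in Treg against 101 ± 58.7 (SD, n = 10) in Tconv. In CD8 cells TSHZ2 was at 0.267 ± 0.281 CPM (SD, n = 9) against 49.3 ± 19.3 (SD, n = 10) in Tconv. MKI67, a gene of dividing cells, averaged 293 ± 162 CPM (SD, n = 7) in Treg, 44.3 ± 57.5 (SD, n = 10) in Tconv and 71.3 ± 72.6 (SD, n = 9) in CD8 cells.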
